A study of Mus musculus with 8 samples.

How the data were processed

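Gene expression was measured by sequencing polyadenylated RNA in 8 mouse brain libraries, 4 labelled Model (PCPA) and 4 labelled IsoL (isoliensinine). Per the labels, RNA was extracted with Trizol, 3 µg went into each library, fragments of 400 to 500 bp were taken after random priming, and 15 PCR cycles were run. No strand marking is stated, so reads of overlapping antisense genes cannot be separated. The submitters' processing notes name fastp 0.22.0 for trimming, HISAT2 2.1.0 for alignment and HTSeq 0.9.1 for counting. The genome build and annotation release are not given in the sources used here; of 21851 gene identifiers shared with GENCODE M21, 517 have the same start as in GRCm38, so coordinates are printed only as the deposited table gives them.

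The deposited table holds read counts per gene and library, per the file headers. It also holds deposited FPKM values, which were checked against the counts, the table's gene length and each library's summed counts, with a largest relative difference of 1.11e-09 in the totals for genes over 200 counts. Gene length is the other deposited unit and entered only a check for length trends. All tests used the counts. The table lists 21959 genes, 51 of them without a symbol. Summed counts ran from 14262836 to 21620466, with 16669 to 17183 genes detected, and 3 counts correspond to 0.138 to 0.210 CPM (counts scaled to a common library size), a floor that covers counting error only. Mitochondrially encoded genes took 4.69 to 5.64% of counts and the 50 most abundant genes 12.3 to 12.9%. No pair of libraries in a group was a duplicate: the smallest chi-square per degree of freedom between them was 2.57.

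Groups were taken from the sample labels, and the single comparison is IsoL minus Model. Genes were filtered with filterByExpr, which kept 14536, scaled with TMM (factors 0.983 to 1.01) and tested in edgeR 4.0.16 (R 4.3.3) with the robust quasi-likelihood F-test and the Benjamini-Hochberg adjustment at 0.05; the common biological coefficient of variation was 9.06%. At an unadjusted p under 0.05 there were 1922 genes, against 727 by chance. The standard error is the absolute log2 fold change divided by the square root of F, and 95% intervals use the t distribution with the fit's degrees of freedom. Low-count folds depend on the prior count. Means and SDs are of CPM over the 4 libraries of a group.

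Gene lists were written before the data were examined, as were the main tests, the rule for naming genes and the first set of alternatives. Of 39 lists, 37 were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on logCPM with a prior count of 2; the pituitary list had fewer than 5 tested genes and the sex-linked list served only as a label check. Camera with an estimated correlation and fry were run beside it. A list score is the mean over members of the logCPM centred per gene. The 25 lists described were chosen after the list results were seen: all that passed, plus lists tied to the treatment and tissue. GO and KEGG terms with 15 to 300 tested genes, as attached in the deposited table, were tested with camera in the same way. Separation of whole profiles was tested by exact permutation over 35 splits on Euclidean distances of logCPM.

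Named were, in each direction, the 10 genes with the smallest adjusted p among those that passed and the 5 with the largest change among those that passed with a mean of at least 1 CPM in a group; from each described list up to 4 members that passed, or else the 2 with the smallest p; and a fixed set with Tph2, Slc6a4, Htr1a, Htr2a, Gad1, Hcrt, Bdnf, Per1, Fos and Hdc. This gave 73 genes, of which 69 are described and the others are not reported here. Any other gene named was chosen after its values were seen, apart from the dorsal midbrain genes of the test for regional mix.

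Alternatives were DESeq2 size factors, no filter on low counts, a replicate block, each library left out in turn, DESeq2 1.42.0 and limma voom with quality weights as other tests, other thresholds, and the 500 most variable genes for the separation. A fit with only IsoL 3 and 4 against Model, a fit with the hypothalamus list score as covariate, and all alternatives for the term tests were added after seeing the data. On simulated data with 14433 genes and 4 against 4 libraries, the main test recovered 38% of 50 genes changed by 25%, 68% of 50 changed 1.5-fold and 94% of 50 changed 2-fold, with 3 false calls among 150. A simulated list of 25 genes shifted by -0.3 log2 was called, and 0 of 39 unshifted lists were (camera). Genes were simulated independently of each other, so this does not show how often lists of correlated genes are called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.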

Results

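The study addressed how isoliensinine, a plant alkaloid, acts on sleep in mice. Polyadenylated RNA from brain tissue was sequenced in 8 libraries. Of these, 4 came from the Model group, labelled as given PCPA (para-chlorophenylalanine, an inhibitor of tryptophan hydroxylase that lowers serotonin), and 4 from the isoliensinine group (IsoL). The series design text describes female ICR mice dosed for 7 days, given pentobarbital 40 minutes after the last dose, and a dissected hypothalamus, whereas the tissue label reads brain. Y-linked genes were read in all 8 libraries, which goes against the stated sex and is taken up below. The design text lists IsoL doses of 12.5, 25 and 50 mg/kg. The labels do not say which of them was sequenced or whether the IsoL mice also received PCPA. Untreated and alprazolam groups were not analysed here, so every direction below is that of IsoL relative to Model. The labels do not state that the libraries of a group came from separate mice, and p-values measure only the spread between these libraries, which may be technical. Summed gene counts were 14262836 to 15886850 in the Model libraries and 15731923 to 21620466 in the IsoL libraries. Values below are CPM, counts scaled to a common library size, as mean ± SD over n = 4 libraries per group, and log2 fold changes with their standard error (SE).

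Genes of the neuronal activity response and of the heat shock response were lower in the IsoL libraries, as were the neuropeptide precursors Pmch and Penk. Hypothalamic regional markers were lower as a set too. For these precursors, an effect of the treatment and a smaller share of hypothalamus in the tissue therefore cannot be told apart. Reln, the potassium channel gene Kcna1 and the homeobox gene Dmbx1 were among the genes that were higher. Of 14536 genes tested, 40 changed at the Benjamini-Hochberg threshold of 0.05 in edgeR's quasi-likelihood test, 17 higher and 23 lower in IsoL. The changes were mostly small, from 1.19-fold to 13.8-fold (the latter Dmbx1, whose fold rests on few counts), and 6 of the 40 genes reached 2-fold. All 40 had non-overlapping libraries between the groups, a pattern that chance gives for 2.86% of genes and that 8.48% of all tested genes showed. Whole profiles parted by group: the mean distance between groups exceeded that within groups by 4.24 in Euclidean logCPM distance (exact permutation test, one-sided, p = 0.0286, the smallest that 35 splits allow). That separation no longer passed without IsoL 1 (exact permutation p = 0.171), IsoL 2 (0.114), IsoL 3 or Model 2 (0.0571 for both). The count of changed genes moved strongly with single libraries, from 6 without Model 4 or without IsoL 2 to 146 without Model 2. Without IsoL 1 it was 8, without IsoL 4 it was 9, without Model 1 it was 13, without IsoL 3 it was 16 and without Model 3 it was 21. Model 2 stood apart from each other library, with a chi-square per degree of freedom of 11.3 to 15.9 in its pairs against 2.57 to 10.1 in all other pairs, and had the highest mitochondrial share of counts, 5.64%. Of the genes named below that did not pass in edgeR, 18 passed in DESeq2 and 7 in limma voom. Of the 28 genes named below that passed, 5 passed without each of the 8 libraries in turn (Dnajb1, Caln1, Arl6ip5, Fos and Reln), and each of the other 23 lost its call in at least 1 of those fits. Pmch, Penk, Dmbx1, Coq2, Zdhhc2, Armc10, Fosl2, Dusp1 and Trpv4 each lost it in 7 of the 8 fits.

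Immediate early genes, which neurons transcribe within minutes of activity, fell in IsoL. Fos (ENSMUSG00000021250, chromosome 12, 85520664 to 85524047 in the deposited table's coordinates, whose genome build is not given in the sources used here), the standard marker of recent neuronal firing, went from 39.7 ± 6.07 CPM in Model to 22.1 ± 1.62 in IsoL, a log2 fold change of -0.85 (SE 0.10, edgeR adjusted p = 0.00486). Egr1, a zinc finger transcription factor induced by synaptic activity, went from 78.0 ± 9.15 to 46.1 ± 6.20 CPM (log2 -0.76, SE 0.11, edgeR adjusted p = 0.0345). Fosl2, of the same family as Fos, fell by 0.47 on the log2 scale (edgeR adjusted p = 0.0393), and Dusp1, a phosphatase of MAP kinases, fell by 0.45 (edgeR adjusted p = 0.0471). Of the 24 members measured, 5 fell, none rose and 19 did not pass. Among all members, 10 fell adjusted over the list alone. As a set the list was lower, with 21 of 24 members below Model and a median log2 change of -0.25 (camera adjusted p = 1.3e-09). This call held with an estimated correlation (adjusted p = 0.0366) and without each library in turn. The list score was 0.12 to 0.15 in the Model libraries, and -0.02 in IsoL 1, -0.00298 in IsoL 2, -0.22 in IsoL 3 and -0.3 in IsoL 4, so most of the difference lay in IsoL 3 and 4. The score of cortical and hippocampal markers also parted these IsoL libraries, at 0.64 and 0.57 in IsoL 1 and 2 and at -0.20 and -0.30 in IsoL 3 and 4.

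Chaperone genes of the heat shock and unfolded protein responses were also lower. Dnajb1 (ENSMUSG00000005483, chromosome 8, 84334822 to 84339282), a co-chaperone of HSP70 and a target of heat shock factor, had the smallest p of all genes and fell from 77.7 ± 2.06 to 53.8 ± 3.61 CPM (log2 -0.53, SE 0.06, edgeR adjusted p = 0.00359). Hspa1a, an inducible HSP70 gene, fell from 2.76 ± 1.39 to 0.357 ± 0.193 CPM (log2 -2.93, SE 0.45, edgeR adjusted p = 0.0344), on 162 counts summed over the Model libraries and 25 over the IsoL libraries. Its value is uncertain because reads can be shared with the near-identical Hspa1b, which went from 7.85 ± 1.07 to 3.90 ± 1.35 CPM and did not pass (edgeR adjusted p = 0.0740; named after its values were seen). Of 25 measured members 2 fell, none rose and 23 did not pass. Among all members, 13 fell and 1 rose adjusted over the list alone. The set was lower with 21 of 25 members below Model and a median log2 change of -0.18 (camera adjusted p = 3.1e-08), also with an estimated correlation (adjusted p = 0.0209). The score was 0.15 ± 0.03 in Model and -0.15 ± 0.03 in IsoL.

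**Figure D1:**
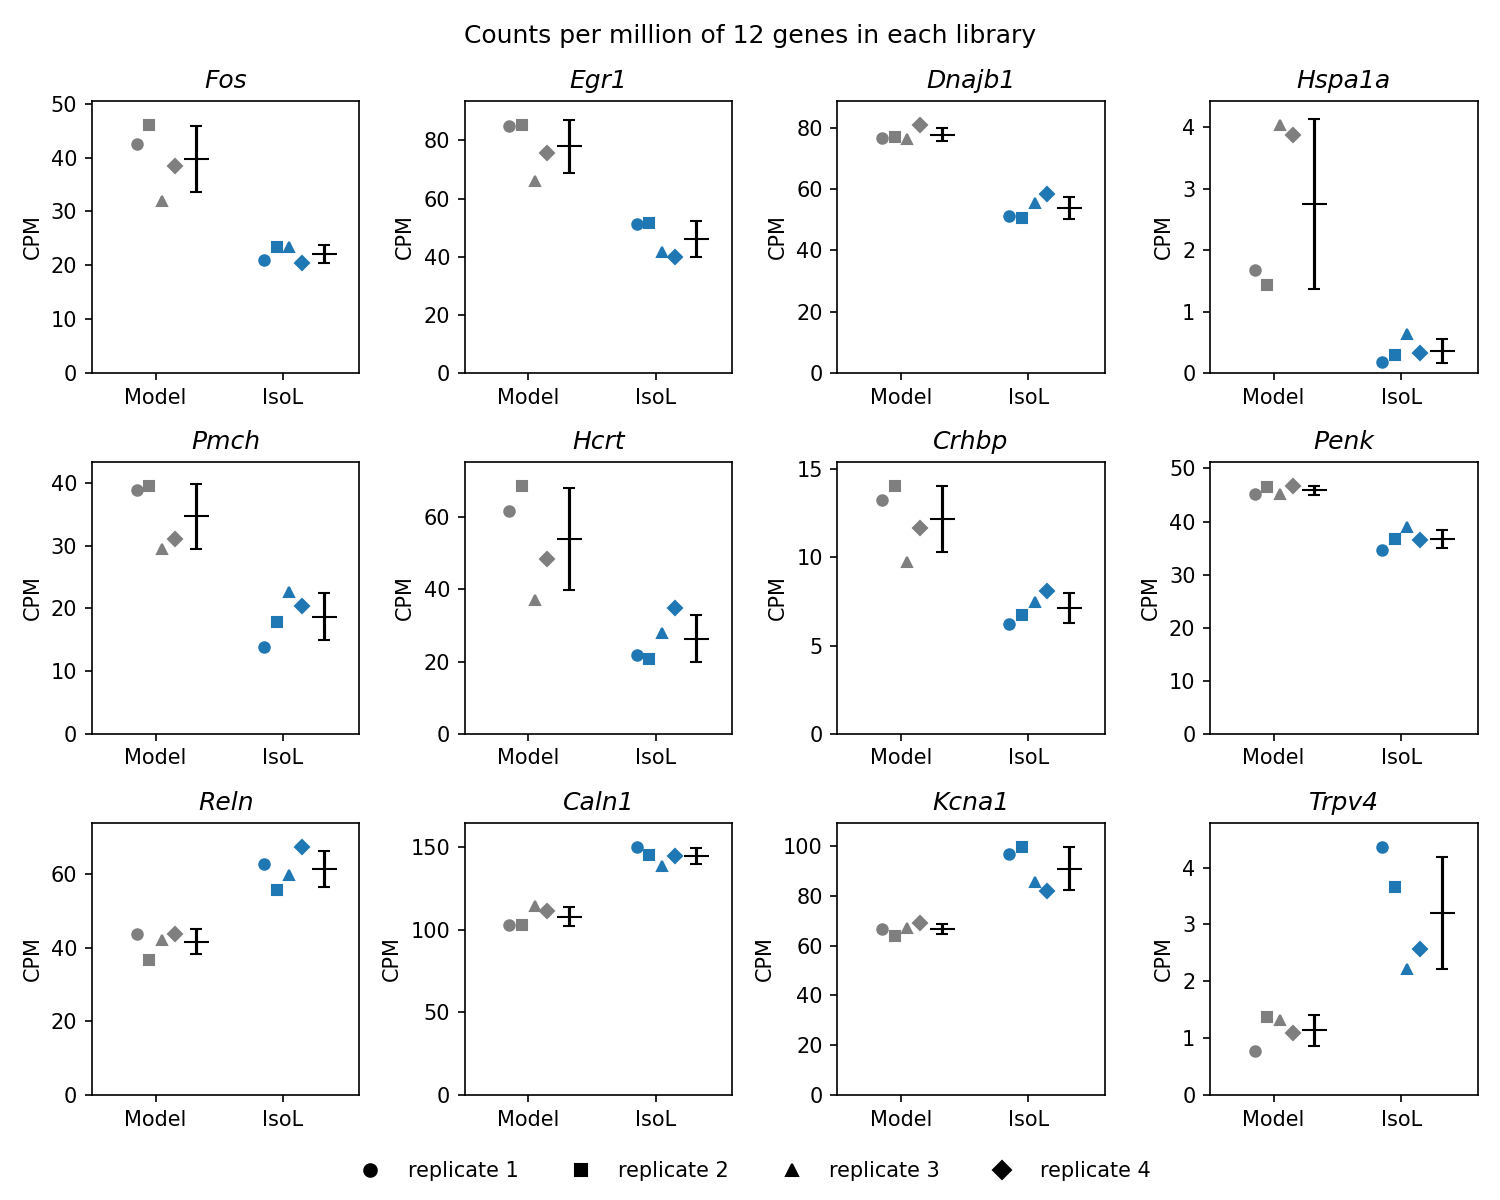
CPM (vertical axes, from 0) of 12 named genes in each of the 4 Model and 4 IsoL libraries; symbols mark replicate numbers, horizontal bars the mean and error bars the SD. In each panel the 2 groups do not overlap, as with Fos at 39.7 CPM on average in Model and 22.1 in IsoL; Hcrt did not pass the gene test (edgeR adjusted p = 0.162).

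The neuropeptide precursor genes Pmch and Penk and the gene Crhbp fell in IsoL, beside the hypothalamic regional markers described below. With the score of those markers as a covariate, chosen after seeing the data, camera's direction for the neuropeptide list turned. Pmch, which encodes the precursor of melanin-concentrating hormone, a peptide of lateral hypothalamic neurons active in sleep, fell from 34.7 ± 5.19 to 18.7 ± 3.73 CPM (log2 -0.89, SE 0.15, edgeR adjusted p = 0.0471). Penk, the enkephalin precursor, fell from 45.9 ± 0.801 to 36.7 ± 1.75 CPM (log2 -0.32, SE 0.06, edgeR adjusted p = 0.0434). Crhbp, which encodes the binding protein of corticotropin-releasing hormone, fell from 12.2 ± 1.89 to 7.13 ± 0.838 CPM (log2 -0.77, SE 0.13, edgeR adjusted p = 0.0429). Hcrt, the precursor of the wake-promoting orexins, was at 53.9 ± 14.0 CPM in Model and 26.3 ± 6.47 in IsoL, with every IsoL library below every Model library, and did not pass (log2 -1.03, 95% interval -1.61 to -0.45, edgeR adjusted p = 0.162). In the list of hypothalamic neuropeptides, 2 of 30 members fell, none rose and 28 did not pass. Among all members, 8 fell adjusted over the list alone. The set was lower (median log2 change -0.25, camera adjusted p = 5.1e-04; adjusted p = 0.389 with an estimated correlation), and its score overlapped between groups. The score was -0.47 in IsoL 1, -0.12 in IsoL 2, 0.0735 in IsoL 3 and -0.0503 in IsoL 4, against -0.0256 in Model 2 and 0.16 to 0.23 in the other Model libraries.

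None of the 23 measured members of the list of hypothalamic regional markers passed alone, yet 22 of them were below Model, with a median log2 change of -0.51 (camera adjusted p = 2.2e-10; adjusted p = 0.207 with an estimated correlation). Among all members, 11 fell adjusted over the list alone. Nkx2-1, a homeobox gene of the ventral hypothalamus, was at 13.9 ± 1.91 CPM in Model and 8.80 ± 1.66 in IsoL (log2 -0.66, SE 0.14, edgeR adjusted p = 0.0687). Hmx2, another hypothalamic homeobox gene, was at 1.57 ± 0.452 and 0.546 ± 0.162 CPM (edgeR adjusted p = 0.0837). The list score lay between 0.20 and 0.27 in the Model libraries and was -0.52 in IsoL 1, -0.19 in IsoL 2, -0.06 in IsoL 3 and -0.17 in IsoL 4. The list of oestrogen and progesterone responsive genes, which shares 2 members with the regional list and 3 with the neuropeptides, was lower too (14 of 15 members below Model, median log2 change -0.31, camera adjusted p = 6.9e-06; adjusted p = 0.207 with an estimated correlation). No member passed alone, and 6 did so adjusted over the list alone. Cckar, a cholecystokinin receptor gene, was at 5.62 ± 0.0981 CPM in Model and 3.51 ± 0.570 in IsoL (edgeR adjusted p = 0.0864). Brs3, the bombesin-like receptor 3 gene, was at 4.15 ± 1.01 and 2.20 ± 0.481 (edgeR adjusted p = 0.116). With the hypothalamus score as a covariate, an alternative chosen after seeing the data, the count of changed genes was 1, while all 40 genes had the same direction. The covariate itself differs between the groups, and with it the group difference of the immediate early score was -0.47 (SE 0.14) against -0.27 (SE 0.07) without it, and that of the heat shock score -0.22 (SE 0.04) against -0.30 (SE 0.02).

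Further genes lower in IsoL were Arl6ip5 (ENSMUSG00000035199, chromosome 6, 97187650 to 97210276), a membrane protein gene that modulates glutamate transport, at 99.0 ± 2.76 CPM in Model and 74.9 ± 3.48 in IsoL (log2 -0.40, SE 0.05, edgeR adjusted p = 0.00486). Cbln1, which encodes the synapse organizer cerebellin 1, was at 125 ± 8.50 and 92.8 ± 8.79 CPM (log2 -0.43, edgeR adjusted p = 0.0345). Ddit4, an inhibitor of mTOR signalling induced by stress, fell by 0.47 on the log2 scale (SE 0.08, edgeR adjusted p = 0.0381). Zdhhc2, a palmitoyltransferase gene, fell by 0.29 and Armc10 by 0.47 (edgeR adjusted p = 0.0345 for both). Dynlt1b, a dynein light chain gene with near-identical copies between which reads can be split, fell by 0.80 (edgeR adjusted p = 0.0478), and its value is uncertain for that reason.

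Among the genes that rose, Caln1 (ENSMUSG00000060371, chromosome 5, 130398296 to 130876253), a brain gene for a calmodulin-like protein, went from 108 ± 5.68 to 144 ± 4.55 CPM (log2 0.42, SE 0.05, edgeR adjusted p = 0.00486). Reln, which encodes the extracellular glycoprotein reelin, went from 41.6 ± 3.38 to 61.3 ± 4.88 CPM (log2 0.56, SE 0.07, edgeR adjusted p = 0.00754). Kcna1, the gene of the voltage-gated potassium channel Kv1.1, went from 66.7 ± 2.17 to 91.0 ± 8.58 CPM (log2 0.45, SE 0.06, edgeR adjusted p = 0.0192). Lmo3, a LIM-only transcriptional regulator gene, rose by 0.48 on the log2 scale and A2m, the alpha-2-macroglobulin gene, by 0.78 (edgeR adjusted p = 0.0345 for both). Coq2, of ubiquinone synthesis, rose by 0.34 (edgeR adjusted p = 0.0434), Xdh, the xanthine dehydrogenase gene, by 0.80 (edgeR adjusted p = 0.0471), and Hif3a, a hypoxia-inducible factor gene, by 0.77 (edgeR adjusted p = 0.0478). Trpv4, a cation channel gating with heat and osmotic pressure, went from 1.14 ± 0.277 to 3.20 ± 0.987 CPM (log2 1.48, SE 0.28, edgeR adjusted p = 0.0478). Pcdhgb6 rose by 1.04 (edgeR adjusted p = 0.0412), an uncertain value because genes of the gamma protocadherin cluster share their 3' exons.

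Among genes that passed, the 3 largest rises were of genes at low levels. Dmbx1, a homeobox gene of the developing midbrain, had 0, 5, 1 and 0 counts in the Model libraries and 38, 16, 14 and 39 in the IsoL libraries (0.0956 ± 0.149 against 1.48 ± 0.703 CPM). The fitted log2 fold change of 3.79 (SE 0.67, edgeR adjusted p = 0.0434) rests on those few counts, and was 3.41 to 5.61 with a library left out, the highest without Model 2. Tfap2d, an AP-2 family gene, went from 25 summed counts in Model to 134 in IsoL (log2 2.1, SE 0.38, edgeR adjusted p = 0.0434). Mab21l2, a gene needed for eye and midbrain development, went from 75 to 266 summed counts (log2 1.55, SE 0.29, edgeR adjusted p = 0.0471).

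Serotonin genes, the system on which PCPA acts, showed no group difference past the threshold in edgeR. Tph2, the neuronal tryptophan hydroxylase gene, was at 6.90 ± 6.54 CPM in Model and 11.7 ± 10.4 in IsoL (log2 0.79, 95% interval -1.79 to 3.37, edgeR adjusted p = 0.794). Slc6a4, the serotonin transporter gene, was at 3.35 ± 3.30 and 8.40 ± 7.76 CPM (edgeR adjusted p = 0.650). Htr1a and Htr2a, receptor genes, had log2 changes of 0.15 (95% interval -0.10 to 0.40) and -0.04 (95% interval -0.22 to 0.14), with edgeR adjusted p = 0.607 and 0.881. Htr2c, a further receptor gene, was at 160 ± 13.4 and 178 ± 6.99 CPM (edgeR adjusted p = 0.275). Slc18a2, the vesicular monoamine transporter gene, was at 126 ± 6.45 CPM in Model and 99.4 ± 10.8 in IsoL (log2 -0.34, edgeR adjusted p = 0.0687), and passed in DESeq2 (adjusted p = 0.00339) and limma voom (0.0361). As a set, none of 19 serotonin genes passed, 1 fell adjusted over the list alone, and the set test gave camera adjusted p = 0.700, with a test direction of higher, a mean log2 change of 0.16 and a median of -0.01.

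GABA genes did not pass as a set either (none of 29 passed, none adjusted over the list alone, median log2 change -0.00457, camera adjusted p = 0.649). Gad1, which makes GABA, was at 412 ± 14.4 CPM in Model and 422 ± 38.4 in IsoL (log2 0.03, 95% interval -0.09 to 0.16, edgeR adjusted p = 0.843). The members with the smallest p were Gabra4 (log2 -0.28, edgeR adjusted p = 0.133) and Gabrq (log2 -0.43, edgeR adjusted p = 0.165). Of 30 glutamate genes none passed, none adjusted over the list alone (camera adjusted p = 0.362). Grm3 had a log2 change of 0.31 (edgeR adjusted p = 0.15) and Slc17a6 of -0.17 (edgeR adjusted p = 0.209). The list of dopamine, noradrenaline, histamine and acetylcholine genes did not pass (19 of 30 members below Model, camera adjusted p = 0.0589), and 3 members fell adjusted over the list alone. Its leading members were the histamine receptor genes Hrh3 and Hrh1. Hrh3 was at 33.7 ± 0.527 and 27.2 ± 2.35 CPM (edgeR adjusted p = 0.0922). Hrh1 was at 18.8 ± 1.30 and 14.3 ± 1.70 CPM (edgeR adjusted p = 0.115). Hdc, which makes histamine, was at 16.1 ± 5.02 and 12 ± 2.44 CPM (edgeR adjusted p = 0.497).

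Receptor genes for neuropeptides and other sleep-related ligands did not pass as a set (22 of 34 below Model, camera adjusted p = 0.279), and 1 fell adjusted over the list alone. Ntsr1, a neurotensin receptor gene, was at 22.2 ± 1.98 CPM in Model and 15.9 ± 1.43 in IsoL (log2 -0.47, edgeR adjusted p = 0.0537) and Mc3r, a melanocortin receptor gene, had a log2 change of -0.52 (edgeR adjusted p = 0.313). Circadian clock genes had 16 of 24 members below Model (camera adjusted p = 0.0555). Adjusted over the list alone 2 fell, Cry1 (log2 -0.31, edgeR adjusted p over all genes = 0.116) and Per2 (log2 -0.25, edgeR adjusted p over all genes = 0.138). Per1 had a log2 change of -0.11 (95% interval -0.25 to 0.04, edgeR adjusted p = 0.541). Bdnf, a neuronal growth factor gene, was at 26.9 ± 4.52 and 23.8 ± 1.62 CPM (edgeR adjusted p = 0.504). Of 29 ion channel genes Kcna1 rose and 28 did not pass. Among all members, 6 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.700). In the glucocorticoid response list of 20, Hif3a rose and Ddit4 fell. Among all members, 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.635, test direction lower, median log2 change -0.01, mean 0.01). Without Model 1 that list gave camera adjusted p = 0.0453. Cholesterol synthesis had 17 of 24 members below Model (camera adjusted p = 0.0605, 1 fell adjusted over the list alone), with Mvk at a log2 change of -0.19 (edgeR adjusted p = 0.377). That set passed without Model 2 (camera adjusted p = 0.0438), without Model 3 and without IsoL 4 (the lowest, 0.00678). The amine list passed without Model 2 (camera adjusted p = 0.0262), without IsoL 1 (0.0454) and without IsoL 2 (0.0440). The clock list did so without Model 2 (0.0438) and without IsoL 2 (0.0256). Over all libraries the amine and clock lists also passed in fry (fry adjusted p = 0.0499 for both).

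Immune and detoxification lists were higher as sets, with no member past the gene test. Interferon-stimulated genes had 22 of 27 members above Model and a median log2 change of 0.29 (camera adjusted p = 0.00754; adjusted p = 0.819 with an estimated correlation), and none passed adjusted over the list alone. Oasl2, an antiviral gene, was at 4.82 ± 0.678 CPM in Model and 6.97 ± 1.80 in IsoL (edgeR adjusted p = 0.242). Irf7, an interferon regulator gene, was at 1.94 ± 0.274 and 3.02 ± 0.691 (edgeR adjusted p = 0.255). The interferon score was 0.40 in IsoL 3 and 0.59 in IsoL 4, against -0.14 in IsoL 1, -0.26 in IsoL 2 and -0.27 to -0.06 in the Model libraries. The score of blood cell markers, a list that did not pass (camera adjusted p = 0.635), was also high in IsoL 3 and 4 (0.36 and 0.34), against -0.19 and -0.30 in IsoL 1 and 2. The interferon call ended without IsoL 3 (camera adjusted p = 0.111) or without IsoL 4 (0.240). Inflammatory and NF-kB genes had 15 of 17 members above Model (camera adjusted p = 0.0124; adjusted p = 0.207 with an estimated correlation), and none passed adjusted over the list alone. Ptgs2, the inducible cyclooxygenase gene, had a log2 change of 0.91 (edgeR adjusted p = 0.165) and Nfkbia, the NF-kB inhibitor gene, of -0.37 (edgeR adjusted p = 0.202). Without Model 1 that call ended (camera adjusted p = 0.0587). Drug metabolism and efflux genes had 15 of 20 members above Model (camera adjusted p = 0.0124; adjusted p = 0.207 with an estimated correlation), and adjusted over the list alone 3 rose. Cyp2d22, a cytochrome P450 gene, was at 39.3 ± 2.83 and 48.8 ± 1.58 CPM (log2 0.31, edgeR adjusted p = 0.0654) and Cyp4f15 had a log2 change of 0.81 (edgeR adjusted p = 0.116).

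Choroid plexus genes had 9 of 10 members above Model and a median log2 change of 1.66 (camera adjusted p = 1.6e-04; adjusted p = 0.491 with an estimated correlation). Adjusted over the list alone 6 rose. The set score was 2.19 in IsoL 1, 1.99 in IsoL 2, 0.25 in IsoL 3 and -0.91 in IsoL 4, against -1.20 to -0.67 in the Model libraries. With only IsoL 3 and 4 against Model, chosen after seeing the data, the call ended (camera adjusted p = 0.0778). Of the 14 called lists, 4 lost their call in that fit, choroid plexus among them. Folr1, a folate receptor gene, was at 0.503 ± 0.175 CPM in Model and 4.37 ± 3.61 in IsoL (edgeR adjusted p = 0.204). Otx2 was at 8.01 ± 2.07 and 14.3 ± 3.65 (edgeR adjusted p = 0.152). Astrocyte genes were higher (13 of 14 above Model, camera adjusted p = 0.00780; adjusted p = 0.247 with an estimated correlation). Adjusted over the list alone 2 rose, the water channel gene Aqp4 at 288 ± 21.1 and 341 ± 22.8 CPM (edgeR adjusted p over all genes = 0.116) and the zinc transporter gene Slc39a12 (log2 0.21, edgeR adjusted p over all genes = 0.118). Oligodendrocyte genes were higher (13 of 16, camera adjusted p = 0.0151; adjusted p = 0.631 with an estimated correlation; none adjusted over the list alone), led by the myelin genes Mobp and Cnp, each with a log2 change of 0.15 (edgeR adjusted p = 0.207 and 0.230). The oligodendrocyte call ended without Model 3 (camera adjusted p = 0.0683) or IsoL 1 (0.198). Microglial genes were higher (12 of 16, camera adjusted p = 0.0451; adjusted p = 0.564 with an estimated correlation; none adjusted over the list alone), with Aif1 at a log2 change of 0.39 (edgeR adjusted p = 0.282). The microglial score was 0.13 and 0.23 in IsoL 3 and 4, where the blood cell score was also high, a link that was not tested. In IsoL 1 and 2 the microglial score was -0.0532 and -0.0767, within the Model range of -0.0887 to -0.0261. That call ended without Model 1 (camera adjusted p = 0.0587), Model 3 (0.0694), Model 4 (0.129), IsoL 3 (0.132) or IsoL 4 (0.276).

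Thalamic markers were lower (11 of 14 below Model, camera adjusted p = 0.0124; adjusted p = 0.564 with an estimated correlation), and 3 fell adjusted over the list alone. Ntng1, a netrin family gene, was at 232 ± 6.23 CPM in Model and 204 ± 9.83 in IsoL (edgeR adjusted p = 0.117) and Pdp1 at 299 ± 6.71 and 259 ± 27.6 (edgeR adjusted p = 0.197). The set call ended without Model 4 (camera adjusted p = 0.0606) or IsoL 4 (0.157). Cortical and hippocampal markers did not pass as a set (camera adjusted p = 0.0791). Of 15 members Lmo3 rose, also adjusted over the list alone, and the set passed without IsoL 3 (camera adjusted p = 0.0242) or IsoL 4 (0.00343). Striatal markers did not pass (camera adjusted p = 0.649). Penk fell, and 1 rose and 2 fell adjusted over the list alone. Cytosolic ribosomal protein genes were lower in 32 of 34 members by small amounts (median log2 change -0.09, camera adjusted p = 5.8e-04; adjusted p = 0.805 with an estimated correlation), and the call ended without Model 2 (camera adjusted p = 0.129). Of the 34 members 1 fell and 33 did not pass. Adjusted over the list alone 1 rose and 1 fell.

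**Figure D2:**
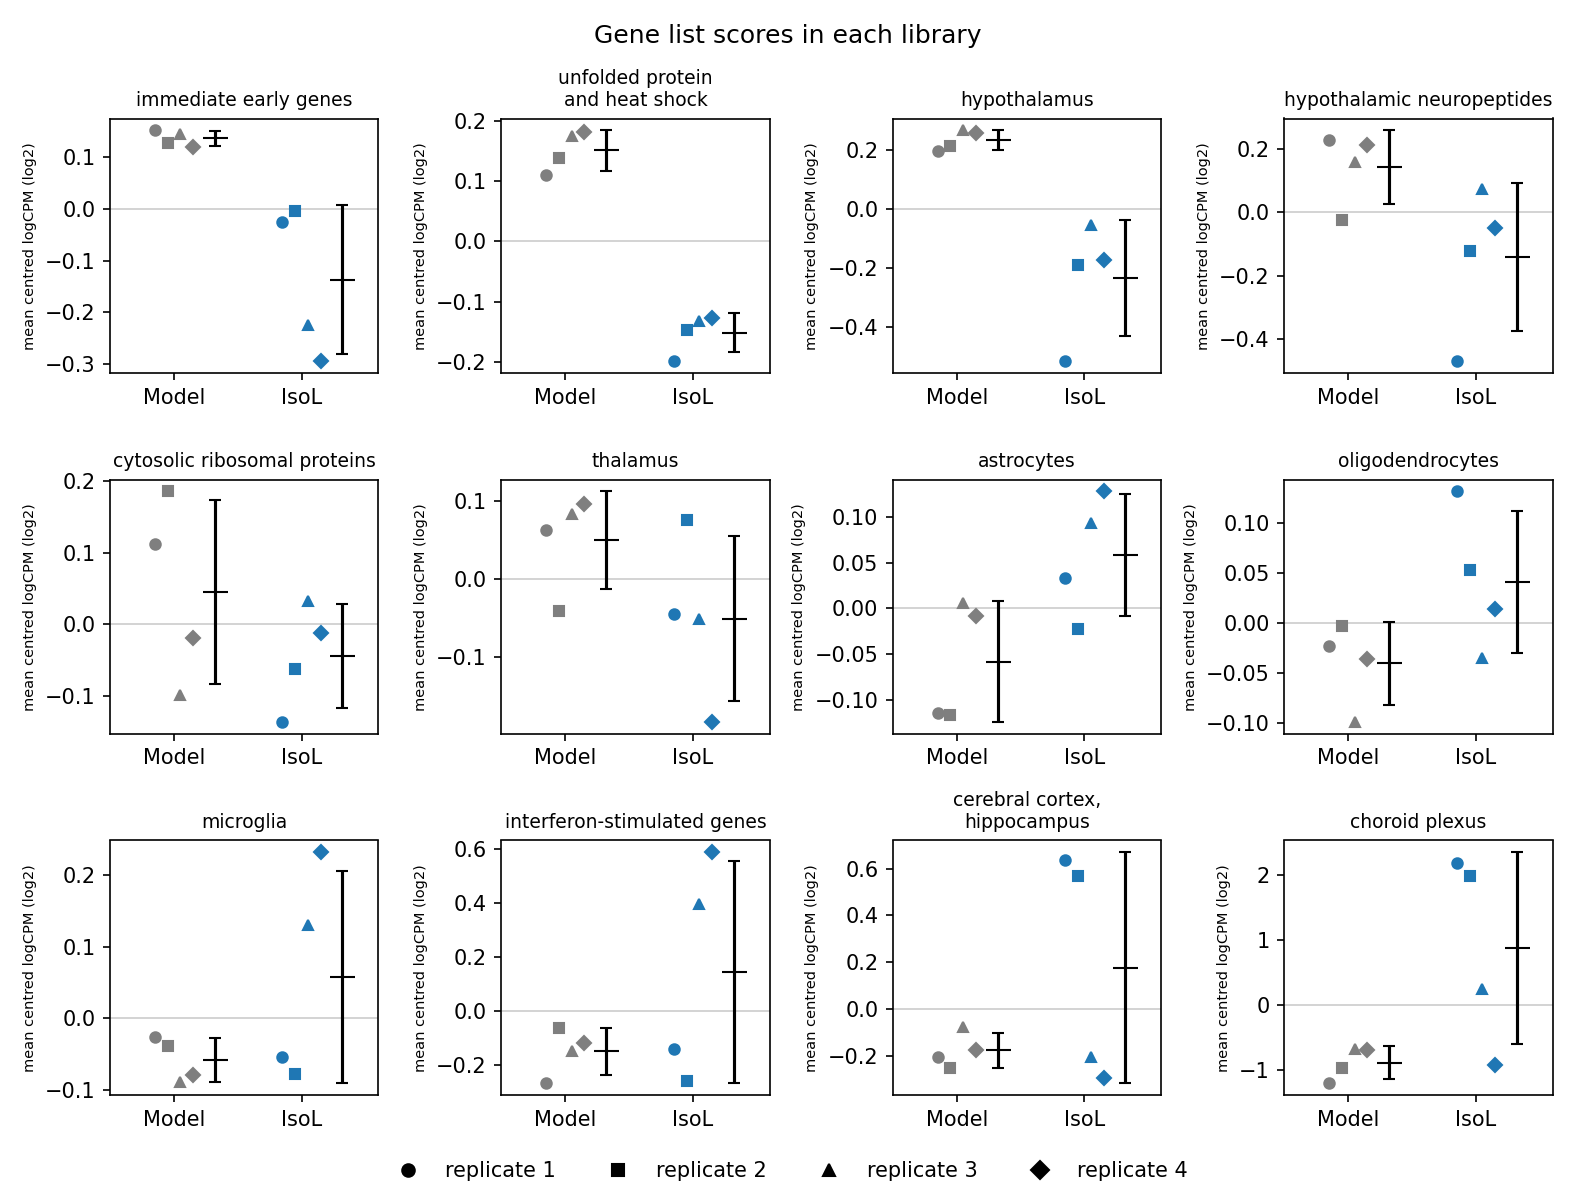
Score of 12 gene lists (mean over members of the logCPM centred per gene, log2 scale, vertical axes) in each of the 4 Model and 4 IsoL libraries; symbols mark replicate numbers, horizontal bars the mean and error bars the SD. Immediate early, heat shock and hypothalamus scores part the groups, while choroid plexus (2.19 and 1.99) and cortical scores are high in IsoL 1 and 2 and interferon scores (0.40 and 0.59) in IsoL 3 and 4.

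Of all 37 lists tested, 7 were higher and 7 lower, and 2 of the 14 held with an estimated correlation, the immediate early and the heat shock lists. The 12 lists not described above did not pass (camera adjusted p = 0.231 to 0.846). Among 2851 GO and KEGG terms that the deposited table attaches to genes, 7 were lower and 4 higher with camera's preset correlation. The lower terms were mainly ribosomal, with the KEGG ribosome pathway of 125 genes first (camera adjusted p = 0.00521), beside chaperone cofactor-dependent protein refolding with 30 genes (camera adjusted p = 0.00631). The higher terms were sperm axoneme assembly with 26 genes (camera adjusted p = 0.00631), cerebrospinal fluid circulation with 18 (0.0102), epithelial cilium movement with 22 (0.0171) and minus-end-directed microtubule motor activity with 20 (0.0298). With an estimated correlation camera passed 0 terms (adjusted p = 0.999 for each term named). 80 had an unadjusted p under the threshold, against 143 by chance, and 294 did with the preset correlation. The term count ran from 2 without Model 2 and 6 without Model 1 to 19 without Model 3 and 20 without Model 4, and was 65 with only IsoL 3 and 4.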

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

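The tests on Y-linked genes were chosen only after the result was seen; the other tests were fixed before their own results were seen, although the patterns they address had been noticed in these data. Of 190 groups of 4 libraries checked, 9 had a library far from the other 3 by Dixon's test, and chance marks about 1 in 20 groups, which is 9.5 here. The oestrogen and progesterone list score was -0.57 in IsoL 1 against -0.11 to -0.03 in the other IsoL libraries. Dnajb1 was at 80.7 CPM in Model 4 against 76.3 to 76.98 in the other Model libraries. Arl6ip5 was at 69.7 CPM in IsoL 3 against 75.9 to 77.1. Hrh3 was at 30.7 CPM in IsoL 2 against 25.9 to 26.3. Cry1 was at 26.3 CPM in Model 3 against 23.0 to 23.5. Per2 was at 23.6 CPM in IsoL 1 against 24.6 to 24.8. Nfkbia was at 12.7 CPM in IsoL 2 against 14.5 to 14.7. Cyp2d22 was at 43.5 CPM in Model 2 against 37.6 to 38.3. Htr2a was at 25.0 CPM in Model 2 against 20.4 to 20.6.

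Among the 35 ways to part the 8 libraries 4 against 4, only the real split (1 of 35) gave as many as 40 genes in edgeR. The highest other count was 5. Chance is therefore unlikely for the gene count but not excluded, since 1 of 35 is the smallest share that these splits allow. For gene lists 5 of the 35 splits gave 14 or more, with 16 as the highest other count, so chance is not excluded for the count of lists. For annotated terms 17 of the 35 splits gave 11 or more, so chance is not excluded there either. The highest other count of terms, 126, came from Model 1, Model 4, IsoL 1 and IsoL 2 against the rest, which points to a structure of the samples other than the groups or to correlated genes within terms under the preset correlation. These were not tested apart.

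Hypothalamic markers were lower in the IsoL libraries. Dmbx1, a homeobox gene of the developing midbrain, and Mab21l2, needed for eye and midbrain development, were higher. IsoL 1, which had the lowest score, is not the whole cause: the scores of IsoL 2, 3 and 4 (-0.19, -0.06 and -0.17) also lay below those of the Model libraries (0.20 to 0.27), and without IsoL 1 the hypothalamus list stayed lower with camera's preset correlation (adjusted p = 7.3e-10, between 2.7e-13 and 2.7e-08 over the 8 fits that each leave out a library; adjusted p = 0.207 with an estimated correlation over all libraries). A different mix of brain regions in the dissected tissue may account for the pattern, and was tested on 7 dorsal midbrain genes not looked at before. They were the tested members of Tal1, Gata2, Lhx1, Lhx5, Barhl2, Pou4f3, En2 and Sox14. Members also expressed in the hypothalamus would weaken this test, and that was not checked. The median log2 change of these 7 genes, 0.17, lay at percentile 93.1 of random lists matched on expression (95% of them between -0.17 and 0.22). Of the 7, 4 were higher and 0 passed in edgeR, which does not decide. An effect of the treatment and a difference in dissection cannot be told apart here, since each group's dissection is not described. Choroid plexus transcripts did vary widely within the IsoL group, with list scores of 2.19 in IsoL 1 and -0.91 in IsoL 4. The group label cannot explain that spread.

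Immediate early and heat shock genes were lower together in the IsoL libraries. With the hypothalamus score as a covariate the group difference of their joint score was -0.34 (95% interval -0.52 to -0.17) against -0.29 without it; the immediate early difference grew from -0.27 to -0.47 (-0.83 to -0.12) and the heat shock difference shrank from -0.30 to -0.22 (-0.31 to -0.13). All 3 intervals exclude 0, so the differences remained after adjustment for this score. The score does not overlap between the groups, so the adjustment extrapolates. It cannot exclude the regional mix that this score tracks, and other mixes stay open too. Their joint median of -0.19 lay at percentile 0 of 10000 random lists matched on expression and length (95% of them between -0.06 and 0.03), which argues against a trend with either. A lower activity and stress response at the time of death under IsoL, or a difference in handling or in time between pentobarbital and dissection, may each stand behind it, and neither was tested.

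Y-linked genes, whose list was left out of the list tests, were read in every library of a series whose design text names female mice. The lowest values over the 8 libraries were 140 CPM for Ddx3y, 37.4 for Uty, 43.2 for Kdm5d and 58.8 for Eif2s3y, above the floor of 3 counts. Each gene held at least 35.3% of its X-linked homologue's count, and Uty held 78.3 to 175% of that of Kdm6a. Such shares argue against reads of the homologues as the whole source, although the share of reads that are misplaced was not measured. All 8 libraries had all 4 genes over 10 CPM. Female animals carry no Y chromosome, so these levels argue against tissue from female animals alone, in every library. The level did not part the groups, and the sex of the mice is otherwise known only from the design text.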

How the results depend on the processing

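The fit with only IsoL 3 and 4, the hypothalamus covariate and all alternatives of the term tests were chosen after the data were seen. All 40 genes had the same direction in each alternative fit. Since their libraries do not overlap between the groups, leaving out libraries or changing the test or scaling could hardly have turned it. The gene count of 40 was 38 with DESeq2 size factors, 74 without a filter on low counts, 17 with a replicate block and 6 to 146 with a library left out. It was 312 in DESeq2 and 175 in limma voom, each including all 40, and 18 of the named genes that did not pass in edgeR passed in DESeq2 and 7 in limma voom; it was 31 with only IsoL 3 and 4, sharing 10, and 1 with the covariate, sharing 0. Other thresholds gave 6 genes (adjusted p and 2-fold), 84 (unadjusted p and 2-fold) and 138 (adjusted p under 0.1). The count of 14 lists was 12 to 16 with a library left out, 6 with the covariate, 2 with an estimated correlation in camera and 8 in fry. Of the 14 called lists, 6 passed in fry, beside 2 lists that camera had not called. With the covariate 4 of the 14 kept their call, 5 lost it in the same direction and 5 turned direction. The count of 11 terms was 2 to 20 with a library left out, 65 with only IsoL 3 and 4, 36 with the covariate and 0 with an estimated correlation in camera. The exact permutation p of the separation was 0.0286 to 0.171 with a library left out and 0.125 with the block (the smallest that 8 arrangements allow). With only IsoL 3 and 4 that p was 0.467. There the mean distance between groups exceeded that within groups by 0.70, against 4.24 with all libraries. In that fit 15 splits are in any case too few to pass the threshold. The labels do not state that libraries of the same number were paired. Their deviations correlated across genes at 0.0199 to 0.0696, against -0.139 to 0.143 in the other pairs between groups. Such values neither show nor exclude a pairing.

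With the covariate, camera's direction turned for the lists of glutamate (adjusted p = 0.229), hypothalamic neuropeptides (0.15), glucocorticoid response (0.407), channels (0.628), oligodendrocytes (0.0739), choroid plexus (0.407), cortex and hippocampus (0.229), hypothalamus (0.267) and oestrogen (0.267). The covariate is built from the hypothalamus list and differs between groups, so its effect and that of the group are only partly separable. It also turned the log2 change of Gabrq (0.0396), Grm3 (-0.046), Tph2 (-0.69), Slc6a4 (-0.83), Htr1a (-0.45), Htr2a (0.0729), Gad1 (-0.25), Per1 (0.0738) and Hdc (0.0862), none of which passed in edgeR without it. With only IsoL 3 and 4, camera's direction turned for glutamate (adjusted p = 0.601), channels (0.548) and cortex and hippocampus (0.352), and the log2 change for Htr1a (-0.0133), Htr2a (0.0094) and Gad1 (-0.0758). In limma voom Htr2a was at 0.0258. With a library left out the direction turned in some fits for serotonin (camera adjusted p = 0.586 to 0.993), GABA (0.428 to 0.993), glucocorticoid response (0.0453 to 0.945) and channels (0.504 to 0.929), and for Htr2a (-0.0656 to 0.0413) and Gad1 (-0.0187 to 0.0705). Apart from the covariate's construction and the fewer libraries, the cause was not tested. A pseudocount of 0.1 was not run, since counts are deposited. Depth limits genes such as Dmbx1, with 6 counts over the Model libraries.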

Other observations

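All genes and sample sets in this part were chosen after their values were seen. In some transcripts IsoL 1 and 2 stood apart from IsoL 3 and 4, and in others the libraries grouped differently. Such differences lie within the group labelled IsoL, so the contrast of IsoL with Model cannot account for them. Ttr, the transthyretin gene that choroid plexus expresses strongly, was at 609 CPM in IsoL 1 and 521 in IsoL 2, at 44.8 in IsoL 3 and 0.458 in IsoL 4, and at 1.06 to 4.59 in the Model libraries. Neurod2, a transcription factor gene of cortical excitatory neurons, was at 16.2 and 12.3 CPM in IsoL 1 and 2, at 1.14 and 2.38 in IsoL 3 and 4, and at 0.883 to 1.47 in Model. Slc17a7, the cortical vesicular glutamate transporter gene, was at 160 and 146 CPM in IsoL 1 and 2 and at 78.0 and 59.9 in IsoL 3 and 4. Rpl3, a ribosomal protein gene, was at 216 and 215 CPM in IsoL 1 and 2, at 329 and 337 in IsoL 3 and 4, and at 325 to 356 in Model. H2-K1, a class I histocompatibility gene, was at 33.4 and 38.1 CPM in IsoL 3 and 4, against 11.4 and 11.02 in IsoL 1 and 2 and 3.90 to 15.6 in Model. B2m, its partner chain, was at 95.3 and 116 CPM in IsoL 3 and 4 and at 49.1 and 46.1 in IsoL 1 and 2.

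Of genes for transcription factors of the dorsal midbrain or habenula, 4 picked for their high values in IsoL did not pass, and of the 7 dorsal midbrain genes not looked at before 4 were above Model. Dmbx1 and Mab21l2, described above as genes of midbrain development, did pass, each at low levels. Tfap2b was at 2.06 ± 1.42 CPM in Model and 13.2 ± 6.15 in IsoL (edgeR adjusted p = 0.121), Pou4f1 at 7.82 ± 2.76 and 15.3 ± 3.24 (edgeR adjusted p = 0.162), Pax3 at 0.665 ± 0.386 and 2.21 ± 0.668 (edgeR adjusted p = 0.0922) and Gata3 at 2.95 ± 0.774 and 5.99 ± 1.38 (edgeR adjusted p = 0.0770). Thalamic markers had a median level of 224 CPM in Model and 218 in IsoL, hypothalamic markers 10.53 and 8.35, and cortical and hippocampal markers 12.6 and 18.2. Tph2, which neurons of the raphe nuclei express, was at 20.02 and 21.4 CPM in IsoL 1 and 4, at 3.36 and 2.21 in IsoL 2 and 3, and at 1.001 to 14.1 over the Model libraries. Slc6a4 was at 16.9 and 13.1 CPM in IsoL 1 and 4 and at 2.26 and 1.39 in IsoL 2 and 3.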
